A study of Danio rerio with 12 samples.

How the data were processed

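RNA sequencing measured transcripts in whole kidneys of adult male zebrafish of the EK strain, aged 4 to 12 months, in 12 libraries. Per the labels, every fish had its heart muscle cells ablated by 17 h in 0.5 to 0.7 µM tamoxifen, and kidneys were collected 7 days after the incubation. The labels name 4 groups of 3 libraries each: wild types and homozygous knockouts of cebpd, and wild types and homozygous knockouts of CEN. There were no fish without heart injury. The labels number the replicates and do not say whether each library came from 1 fish, so p-values measure the spread between these libraries. They also do not say what the CEN lesion removes or which part of cebpd was altered.

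The authors deposited 1 table of raw read counts per gene symbol for each library, with no normalization. Per the submitters' processing notes, Trim Galore 0.6.4, TopHat2 2.1.1, HTSeq and the genome build danRer10 were used. The notes as read here give no roles, and the annotation and strand setting are not given in the sources used here. Without a stated strand, reads of overlapping antisense genes cannot be told apart, and reads of near-identical paralogs may have been shared or dropped. Each table held 14781 genes and 5 summary lines, which were left out of library sizes and tests. Reads in no gene made up 32.1 to 38.5% of a file's total and reads in more than 1 gene 1.32 to 3.99%. Counts in genes were 15793475 to 18104535 per library, so 3 counts corresponded to 0.166 to 0.19 CPM, the usual unit of counts relative to library size. This floor covers counting error only.

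Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with a minimum count of 10, which left 11840 genes. Libraries were scaled by TMM, with factors from 0.835 to 1.1, and CPM values use these factors. The main test was edgeR's quasi-likelihood test with a term for each of the 4 groups over all 12 libraries, which leaves 8 residual degrees of freedom. Contrasts were knockout minus wild type in each experiment, the difference between these effects, and CEN wild types minus cebpd wild types. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. The common biological coefficient of variation was 25.3%.

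Before the data were examined, 32 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested members were tested by camera in limma with a preset correlation between genes of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were alternatives. The rule named, for each knockout comparison, cebpd, and up to 12 genes of largest increase and 12 of largest decrease among genes past the threshold with at least 1 CPM in a group and no overlap between groups. With fewer than 5 such genes it added those of lowest p up to 10 in all, given as not past the threshold. It also named up to 4 called members of each list, or the 2 members of lowest p where none was called, all members of the C/EBP list, up to 12 genes called in both comparisons, and up to 8 genes each for the difference of effects and for the wild types. Genes known only by an identifier were passed over unless no other was left.

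Other alternatives were DESeq2's size factors, scaling without the 20 most abundant genes, no filter, a filter of 10 CPM in 3 libraries, the DESeq2 Wald test, limma-voom, a Spearman correlation, fits on the 6 libraries of an experiment, the replicate number as a block, a covariate for tissue composition, thresholds of 0.1 and of a log2 change of 1, and leaving out each library. The composition covariate was the mean log2 CPM of the proximal and distal tubule lists minus that of the neutrophil, erythroid and B cell lists. It can therefore also remove differences in those lists, such as that of neutrophil genes in cebpd KO. edgeR with robust estimation, limma-voom with sample quality weights, and fits without libraries that stood apart were added after seeing the data. Gene symbols were matched to a RefSeq gene table of the newer assembly GRCz12tu, 12660 by symbol and 1832 by a synonym, with 289 unmatched. That table was used for newer names, for the chromosome on which a gene lies and for gene order. Its coordinates belong to another build and are not given.

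The tests were tested on simulated data with the real library sizes, mean levels and spread over 11840 genes, with 200 genes changed, 50 at each of 4 sizes. The heat shock list was also lowered in the simulated knockouts, and calls among its genes were not counted as false. Apart from this all 4 groups had the same mean levels, so the experiments did not differ. For the cebpd comparison edgeR recovered 9% of genes changed 1.5-fold, 36% of those changed 2-fold, 79% of those changed 4-fold and 92% of those changed 8-fold, and 2.6% of its calls were false. For the CEN comparison it recovered 6%, 34%, 90% and 99%, and 3.8% of its calls were false. With DESeq2, 18.5% of calls were false for the cebpd comparison and 16.5% for the CEN comparison. Replicate pairs of each group differed by more than sampling noise, with a chi-square per degree of freedom of 26.8 to 86.9, so all libraries were counted singly. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.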

Results

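Transcripts were counted in 12 whole-kidney libraries of adult male zebrafish whose heart muscle cells had been ablated 7 days earlier. The adult zebrafish kidney holds nephrons, blood-forming marrow and the steroid-producing interrenal tissue. The 4 groups had 3 libraries each, cebpd wild types (cebpd WT), cebpd knockouts (cebpd KO), CEN wild types (CEN WT) and CEN knockouts (CEN KO). Per the series title, the study asked which kidney genes the transcription factor Cebpd regulates during heart regeneration. The labels do not say what CEN is. Gene counts were 15793475 to 18104535 per library. All groups were injured, so the values compare genotypes after injury and not injured with uninjured kidneys.

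The cebpd transcript was nearly lost in the cebpd knockouts, and in the CEN knockouts it lay below all wild types without passing the main test. It stood at 373 CPM ± 81.2 (SD, n = 3) in cebpd WT and 9.1 CPM ± 4.56 (SD, n = 3) in cebpd KO. This is a 41.2-fold fall, a log2 fold change of -5.36 ± 0.38 (SE), with an adjusted p of 9.43e-05 by edgeR's quasi-likelihood test. In CEN WT it stood at 279 CPM ± 61.9 (SD, n = 3) and in CEN KO at 72.8 CPM ± 5.01 (SD, n = 3). The highest CEN KO library had 77.9 CPM and the lowest CEN WT library 212 CPM. The CEN difference was 3.84-fold, a log2 fold change of -1.94 ± 0.32 (SE), and missed the threshold over all genes with an adjusted p of 0.106. Adjusted over the list alone, cebpd passed among the 7 C/EBP genes in both comparisons. It also passed in the CEN comparison with the DESeq2 Wald test (2.5e-06), limma-voom (0.0487), limma-voom with quality weights (0.00433), the composition covariate (0.0328), only the 6 libraries of the experiment (0.0425), and without cebpd KO replicate 2 (0.00776). Over all alternatives its adjusted p ran from 2.5e-06 to 0.546. The loss of cebpd transcript was deeper in cebpd KO than in CEN KO by 3.42 on the log2 scale, a log2 difference of -3.42 ± 0.46 (SE) with an adjusted p of 0.0244.

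**Figure D1:**
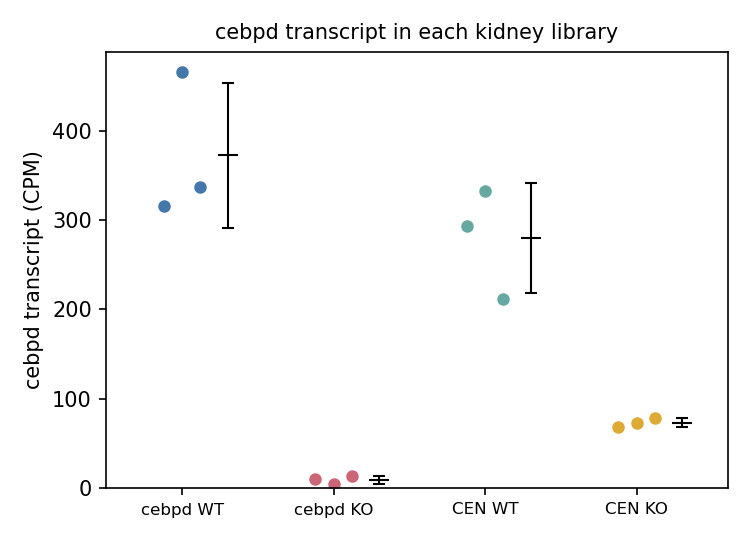
The cebpd transcript in CPM (linear axis from 0) in each of the 12 libraries, with points for libraries and bars for the group mean ± SD (n = 3). Group means were 373, 9.1, 279 and 72.8 CPM, and no knockout library reached its wild types.

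In the cebpd knockouts a small set of genes changed besides cebpd, among them 2 of the heat shock list and an ammonia transporter. The chaperone gene hsp90aa1.2 fell from 465 CPM ± 137 to 91.9 CPM ± 23.6 (SD, n = 3), 5.06-fold, and the co-chaperone gene dnaja1 fell from 46.9 CPM ± 4.32 to 18.6 CPM ± 3.54 (SD, n = 3), 2.52-fold. The kidney and gill ammonia transporter gene rhbg fell 2.15-fold, from 68.3 CPM ± 8.47 to 31.7 CPM ± 5.03 (SD, n = 3). rgs8, a regulator of G-protein signalling, fell from 8.98 CPM ± 5.32 to 0.41 CPM ± 0.202 (SD, n = 3). The ras gene hrasa rose 1.84-fold, from 24.1 CPM ± 2.35 to 44.3 CPM ± 0.094 (SD, n = 3), and zgc:56530, named cst14a.2 in the newer table, rose 2.08-fold.

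By edgeR's quasi-likelihood test 10 of 11840 genes passed, 2 higher and 8 lower, all with no overlap between the groups, where chance gives 10% of genes without overlap and 16% of all genes had none. Log2 fold changes were -4.44 ± 0.59 (SE) for rgs8 and -2.34 ± 0.32 (SE) for hsp90aa1.2, each with an adjusted p of 0.0181. slc25a25b, which encodes a mitochondrial nucleotide carrier, changed by -1.63 ± 0.26 (SE, adjusted p 0.0487), and akap2, an anchor of protein kinase A, by -1.50 ± 0.18 (SE, adjusted p 0.0124). dnaja1 changed by -1.33 ± 0.18 (SE, adjusted p 0.0181), rhbg by -1.11 ± 0.18 (SE, adjusted p 0.0487) and nabp1a, a single-stranded DNA binding protein gene, by -0.82 ± 0.12 (SE, adjusted p 0.0354). The increases were 1.05 ± 0.13 (SE, adjusted p 0.0147) for zgc:56530 and 0.88 ± 0.13 (SE, adjusted p 0.0312) for hrasa. At an adjusted p under 0.1, 134 genes passed, and 1584 genes had an unadjusted p under 0.05 where chance gives 592. Calls numbered 410 with DESeq2, 351 with quality weights, 197 with the replicate block and 63 with the stricter filter. With the composition covariate 2 genes passed, 1 of them among the 10. With only the 6 libraries of the experiment 1 gene, cebpd, passed, and the adjusted p of the other 9 was 0.114 to 0.247. Calls numbered 233 without cebpd KO replicate 3, 34 without cebpd WT replicate 3, and 1 and 2 without cebpd KO replicates 1 and 2. They numbered 2 and 3 without cebpd WT replicates 1 and 2, and 6, 5 and 6 without CEN WT replicates 1, 2 and 3. Leaving out each of the 12 libraries in turn ended the call of rhbg and slc25a25b in 9 cases each, with an adjusted p of up to 0.224 and 0.172, that of nabp1a in 10 (up to 0.212) and that of hrasa in 8 (up to 0.172). It ended that of dnaja1 in 5 (up to 0.114), that of akap2 in 4 (up to 0.0713), and that of zgc:56530, rgs8 and hsp90aa1.2 in 3 each (up to 0.0612, 0.114 and 0.114). Of the 9 called genes other than cebpd, 8 also differed between the 2 groups of wild types in the direction of the knockout, all but hrasa. That comparison shares the cebpd wild types. Simulations in which the experiments differed without any knockout effect gave a mean of 4 and up to 7 of the 9 genes of lowest p. In most of these simulations no gene passed in the cebpd comparison, so their 9 genes were not called ones. The gene hsp90aa1.2 was at 91.6 CPM ± 28.9 (SD, n = 3) in CEN WT. Its paralog and neighbour hsp90aa1.1, similar in sequence, was at 2.08 CPM ± 0.374 in cebpd WT and 1.8 CPM ± 0.208 in cebpd KO (SD, n = 3), and how the counting shared reads between them is not given in the sources used here. In the newer gene table zgc:56530 lies on the chromosome of cebpd.

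**Figure D2:**
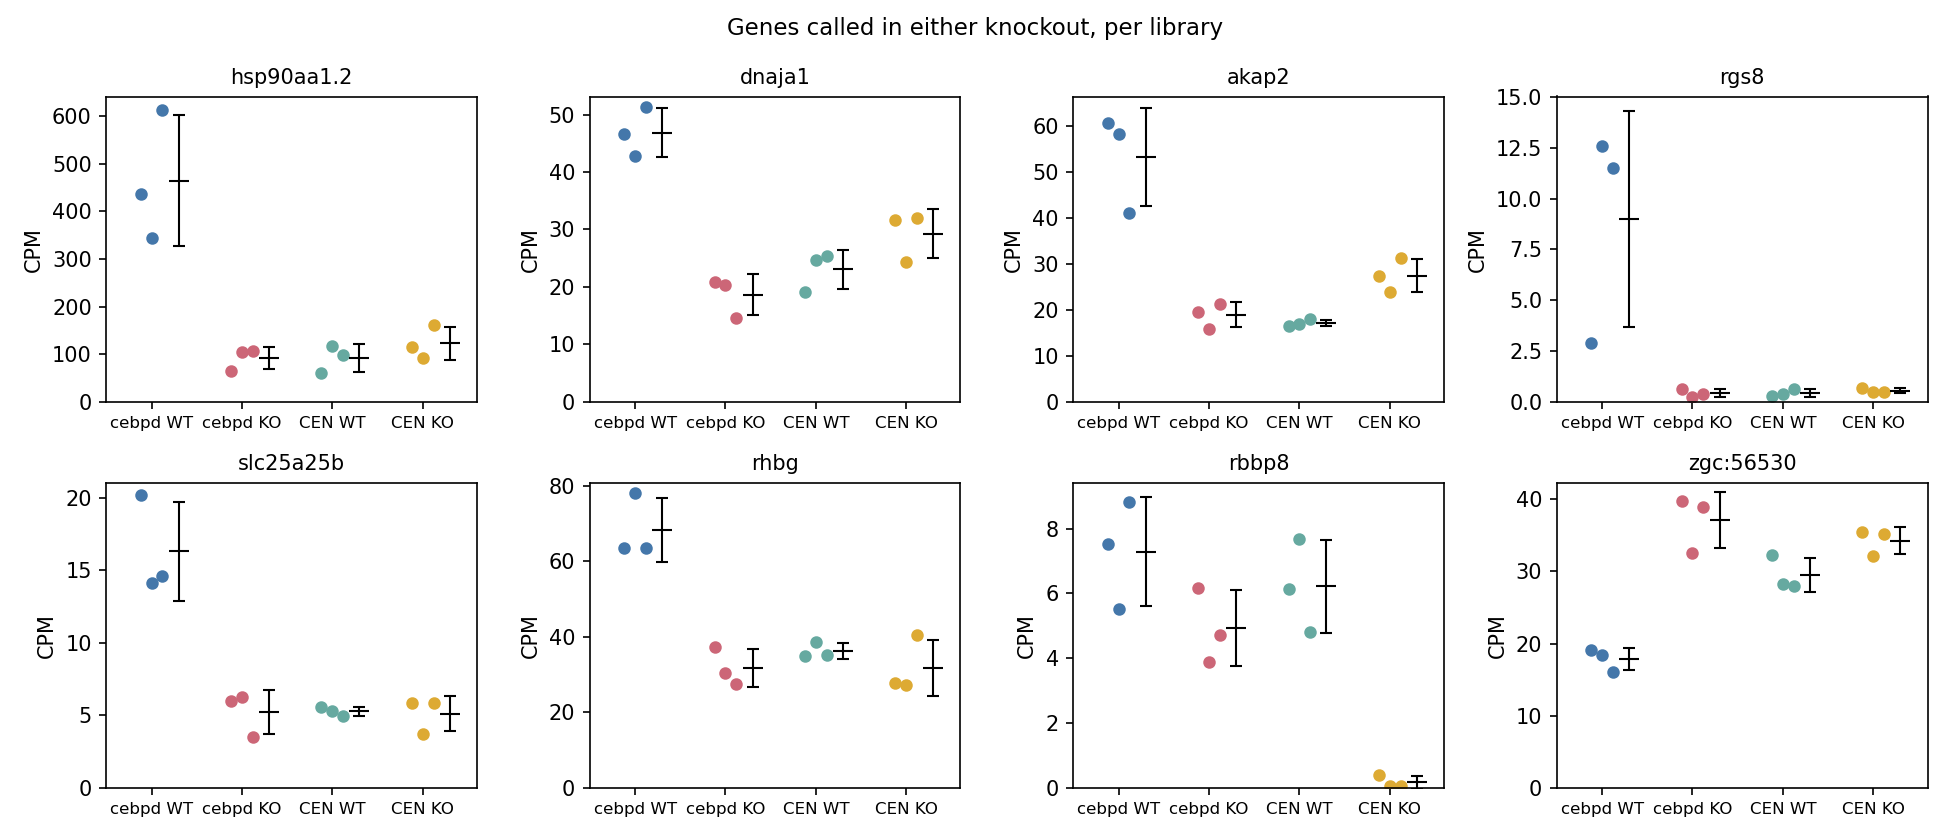
CPM (linear axes from 0) of 8 of the genes called in either knockout, in each library, with bars for the group mean ± SD (n = 3). The chaperone gene hsp90aa1.2 was at 344 to 614 CPM in cebpd WT and at 60.1 to 161 CPM in the other 9 libraries, and rbbp8 was near 0 only in CEN KO.

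By camera with the preset correlation neutrophil and macrophage genes were higher in the cebpd knockouts and genes of protein folding, ciliated cells and interrenal cells were lower. Of these lists protein folding alone kept its call with an estimated correlation. As many lists passed camera in 3 of the 10 splits of the cebpd libraries, the real one included, so their number does not set the real groups apart. Of 26 neutrophil genes 25 lay above 0, with a median log2 fold change of 0.61 and a camera adjusted p of 2.4e-17, which became an adjusted p of 0.172 with an estimated correlation. By fry the adjusted p of the neutrophil list was 0.0354. Its mean log2 CPM was 6.90, 7.12 and 7.06 in cebpd KO against 6.22, 6.61 and 6.49 in cebpd WT. In CEN WT it was 6.73, 6.36 and 6.48 and in CEN KO 6.71, 6.45 and 6.39. Adjusted over the list alone 16 of the neutrophil genes passed. Over all genes edgeR called 0 of the 26 and DESeq2 10, and 18 had an unadjusted p under 0.05. Its lowest p belonged to cpa5 (1.14 ± 0.25, SE) and the sphingosine phosphate receptor gene s1pr4 (0.70 ± 0.15, SE), neither past the threshold over all genes. Of 27 macrophage and monocyte genes 25 lay above 0, with a median of 0.43 (camera adjusted p 6.55e-05, adjusted p 0.498 with an estimated correlation). Without cebpd WT replicate 1 the median was 0.23, and mean log2 CPM was 5.82, 5.88 and 6.02 in cebpd KO against 5.28, 5.85 and 5.59 in cebpd WT. Among them lgals2a was 0.58 ± 0.15 (SE) and slc7a7 -0.64 ± 0.17 (SE). Of 47 heat shock and protein folding genes 39 lay below 0, with a median of -0.39 (camera adjusted p 3.45e-14), and this was the 1 list kept with an estimated correlation, at an adjusted p of 0.0495. Mean log2 CPM of this list was 6.45 in cebpd WT and 5.92 in cebpd KO. It was 5.65 in CEN WT and 5.62 in CEN KO, so the cebpd wild types stood above every other group. Adjusted over the list alone 15 of the 47 passed, and hsp90aa1.2 and dnaja1 passed over all genes. Other members lay near 0, such as hsp90ab1 at 0.16 ± 0.14, hspa4b at 0.01 ± 0.12 and dnaja2 at -0.03 ± 0.13 (SE).

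Of 16 interrenal and chromaffin genes 12 lay below 0, median -0.51 (camera adjusted p 0.0011, adjusted p 0.498 with an estimated correlation), among them the adrenocorticotropin receptor gene mc2r at -1.29 ± 0.31 (SE) and nr5a1a, a regulator of steroid synthesis, at -1.12 ± 0.29 (SE), and without cebpd WT replicate 2 the median was -0.31. Mean log2 CPM of this list was 3.56, 3.17 and 3.41 in cebpd KO against 3.91, 4.31 and 3.53 in cebpd WT, and that of the skeletal muscle list 2.56, 1.44 and 2.02 against 3.1, 3.65 and 1.52. Of 29 multiciliated cell genes 26 lay below 0, median -0.24 (camera adjusted p 0.0011, adjusted p 0.516 with an estimated correlation), with ropn1l at -1.84 ± 0.38 (SE) and the ciliary regulator foxj1b at -0.86 ± 0.20 (SE). The C/EBP list was lower (camera adjusted p 9.33e-05, adjusted p 0.107 with an estimated correlation), with a mean of -0.83 but a median of 0.00. It includes the mutated gene cebpd itself at -5.36, so its call is not separate from the loss of cebpd. Apart from cebpd, its members cebpa (0.00 ± 0.21), cebpb (0.10 ± 0.24), cebp1 (0.09 ± 0.24), cebpz (-0.27 ± 0.15) and ddit3 (0.14 ± 0.16) lay near 0 (SE). cebpg was -0.49 ± 0.11 (SE), with an adjusted p of 0.0849. These 6 lists kept their call by camera with the preset correlation whichever single library was left out.

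The other 9 of the 15 lists past camera lost it when 1 library was left out. Lists of ion and water transport (median -0.16, rhbg the 1 called member), glucocorticoid targets (-0.16, its 1 called member being cebpd itself), distal tubule (-0.27, with mal2 at -0.94 ± 0.25, SE) and skeletal muscle (-1.08) were lower. Their adjusted p with an estimated correlation was 0.469, 0.498, 0.516 and 0.738. Lists of ribosomal proteins (0.27), acute phase and complement (0.28), thrombocytes (0.30), B cells (0.35) and gonad (0.38) were higher. Their adjusted p with an estimated correlation was 0.738, 0.738, 0.462, 0.634 and 0.587. In the acute phase list cp, for ceruloplasmin, was 1.09 ± 0.28 (SE) and lect2l 1.06 ± 0.26 (SE). The ribosomal list had a mean log2 CPM of 9.94, 9.91 and 10.5 in the 3 cebpd KO libraries and 9.79, 9.86 and 10.2 in cebpd WT. Without cebpd KO replicate 3, the library with the lowest scaling factor of 0.835, its median was -0.01, that of ion transport -0.11 and that of the distal tubule -0.22, and without cebpd WT replicate 2 the medians of glucocorticoid targets, ion transport, distal tubule and muscle were -0.05, -0.09, -0.08 and -0.36. Without cebpd KO replicate 1 the medians of acute phase, gonad, thrombocytes, B cells and distal tubule were 0.23, 0.20, 0.16, 0.26 and -0.15. Without cebpd KO replicate 2 those of muscle, thrombocytes and B cells were -0.81, 0.18 and 0.29. Without cebpd WT replicate 3 those of acute phase, gonad, thrombocytes and B cells were 0.35, 0.49, 0.27 and 0.24, and without cebpd WT replicate 1 that of B cells was 0.35. Some medians grew where the call was kept. Those of gonad and acute phase were 1.33 and 0.50 without cebpd WT replicate 2 and 0.78 and 0.47 without cebpd KO replicate 2. That of glucocorticoid targets was -0.32 without cebpd KO replicate 1 and -0.30 without cebpd WT replicate 3. The remaining 17 lists did not pass, among them the proximal tubule (median -0.21, slc15a2 0.96 ± 0.19 and ggt1a -1.02 ± 0.23, SE), podocytes, cytokines, T and NK cells, erythroid cells, blood stem cells, cell cycle, interferon genes, circadian clock genes (nfil3-2 1.57 ± 0.35, SE), oxidative phosphorylation, lipid metabolism, extracellular matrix, kidney injury (hmox1a -1.36 ± 0.42, SE), endothelial cells (apln -0.78 ± 0.17, SE), heart muscle, liver, and pancreas and gut. Some of these passed when 1 library was left out. Medians were then -0.48 and 0.27 for erythroid cells and -0.23 and 0.25 for the cell cycle without cebpd WT replicates 2 and 3, 0.44 and 0.37 for T and NK cells without cebpd WT replicate 2 and cebpd KO replicate 3, and 0.21 and 0.30 for blood stem cells without cebpd WT replicate 1 and cebpd KO replicate 3. They were -0.26, -0.29 and -0.20 for the proximal tubule without cebpd WT replicates 1 and 3 and CEN WT replicate 3, 0.42 and 0.24 for liver without cebpd WT replicate 2 and cebpd KO replicate 2, 0.22 for interferon genes without cebpd WT replicate 3 and 0.24 for clock genes without cebpd KO replicate 3. For oxidative phosphorylation they were 0.15, 0.18, 0.12 and -0.15 without cebpd WT replicate 3 and cebpd KO replicates 1, 2 and 3. Median and direction of the test differed in sign in 3 lists, those of the C/EBP, cell cycle and kidney injury genes.

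**Figure D3:**
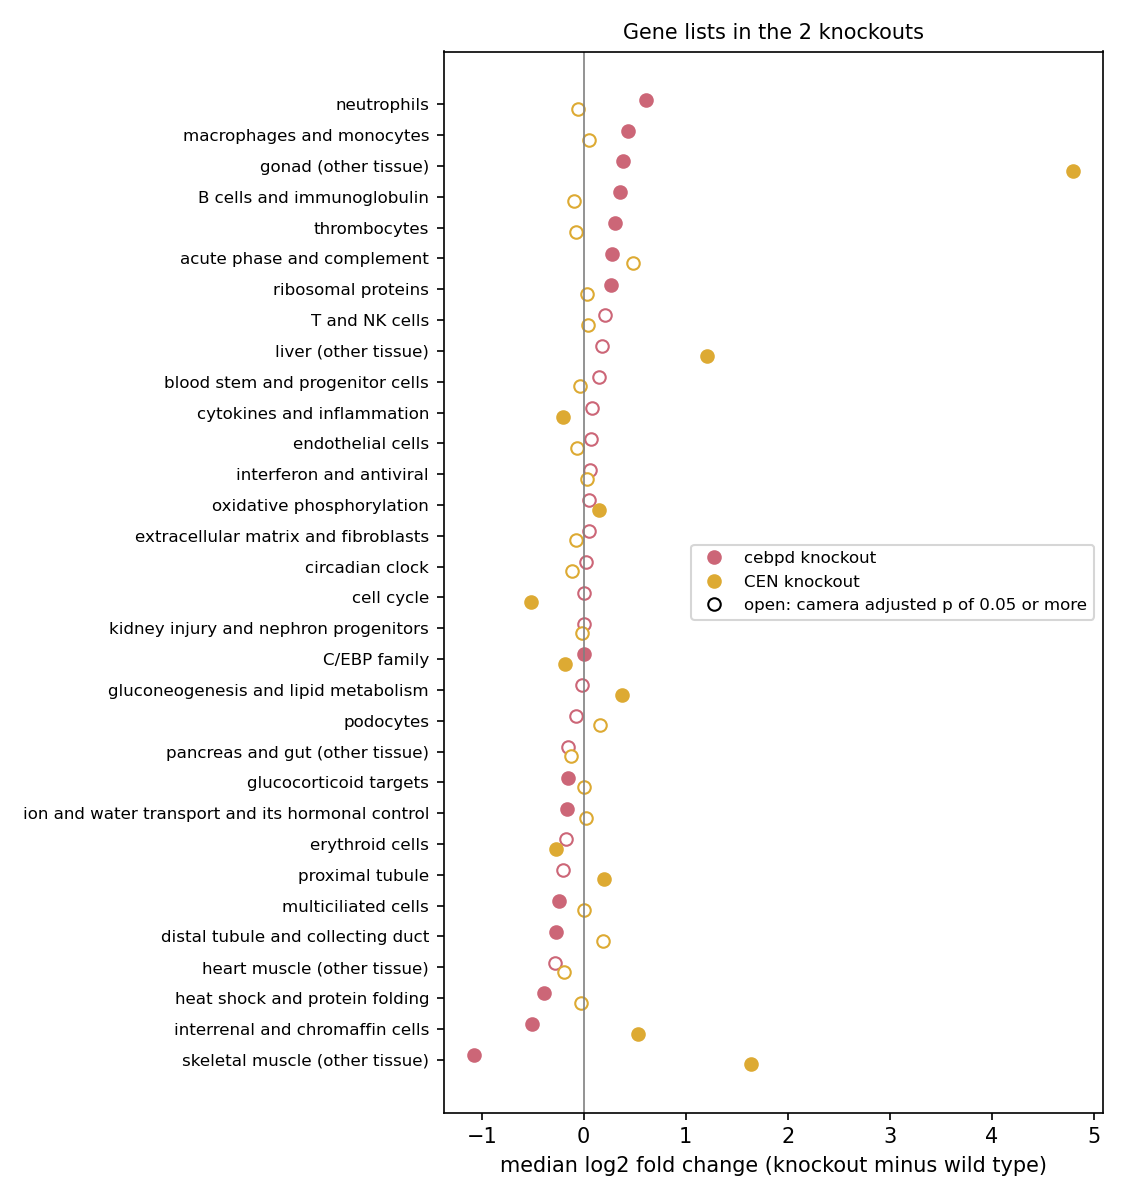
Median log2 fold change (knockout minus wild type) of the 32 gene lists in the cebpd and CEN knockouts, with filled points where camera with the preset correlation gave an adjusted p under 0.05. Neutrophil genes had medians of 0.61 and -0.05, and cell cycle genes 0.00 and -0.52.

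In the CEN knockouts rbbp8, a gene of DNA end resection, was nearly absent. It stood at 6.21 CPM ± 1.44 in CEN WT and 0.169 CPM ± 0.19 in CEN KO (SD, n = 3), with CEN KO libraries at 0.388, 0.0579 and 0.0606 CPM, of which the last 2 lay under the 3-count floor. Its log2 fold change was -5.11 ± 0.50 (SE) with an adjusted p of 0.00365, and it was the 1 gene of 11840 that passed. It kept its call whichever library was left out (adjusted p 0.000713 to 0.0371) and lost it with only the 6 libraries of the experiment, at an adjusted p of 0.0556, while alternatives ran from 2.32e-15 to 0.0556. In the newer gene table rbbp8 lies on the chromosome of cebpd. Of the genes that did not pass, angptl4, an inhibitor of lipoprotein lipase, was at 54 CPM ± 5.98 in CEN WT and 150 CPM ± 21 in CEN KO (SD, n = 3), and cpt1b, which carries fatty acids into mitochondria, at 64.2 CPM ± 19 and 165 CPM ± 26.9 (SD, n = 3).

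Genes of lowest p after rbbp8 did not pass edgeR's test. They were sox4b at -0.97 ± 0.14 (SE) and desi1a at 1.1 ± 0.16 (SE), both with an adjusted p of 0.0606, and angptl4 at 1.47 ± 0.23 (SE), with 0.0966. cpt1b was 1.36 ± 0.23, slc6a13 1.11 ± 0.19, si:dkey-33i11.3 (hpn in the newer table) 1.09 ± 0.19, the clock gene cry2b 0.96 ± 0.17 and ggt1a, a proximal tubule enzyme gene, 1.3 ± 0.23 (SE), each with an adjusted p of 0.106. The cell cycle inhibitor gene cdkn1a was -1.15 ± 0.20 (SE, adjusted p 0.106) and the clock gene nr1d4b -1.50 ± 0.30 (SE, adjusted p 0.14). At an unadjusted p under 0.05 there were 1168 genes where chance gives 592. The number past the threshold was 137 with DESeq2, 193 with quality weights, 66 with the composition covariate, 11 with the replicate block and 5 with limma-voom. It was 2, rbbp8 not among them, with only the 6 libraries of the experiment. It was 7 without CEN WT replicate 3, 2 without CEN KO replicate 2, 2 without cebpd KO replicate 2 and 2 without cebpd WT replicate 2.

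By camera with the preset correlation cell cycle genes were lower in the CEN knockouts and genes of lipid metabolism were higher, but no list kept its call with an estimated correlation. Of the 10 splits of the CEN libraries 9, the real one included, gave as many lists past camera. The number of lists thus does not set the real groups apart. Of 64 cell cycle genes 57 lay below 0, with a median of -0.52 (camera adjusted p 2.97e-19, adjusted p 0.736 with an estimated correlation). Over all genes edgeR called 0 of the 64 and DESeq2 5, 7 passed adjusted over the list alone and 21 had an unadjusted p under 0.05. The replication genes mcm3 and mcm6 were -1.05 ± 0.21 and -1.08 ± 0.22 (SE). Mean log2 CPM of the list was 5.34, 4.38 and 4.46 in CEN KO replicates 1, 2 and 3 against 5.41, 5.43 and 4.92 in CEN WT, and that of the erythroid list was 6.80, 5.86 and 6.38 against 6.82, 6.72 and 6.62. In both lists CEN KO replicate 1 lay within the range of CEN WT and replicates 2 and 3 below it, and without replicate 1 the cell cycle median was -0.91. In replicate 1, which held egg-coat transcripts, ccnb1 was at 155 CPM and ccnb2 at 79.6 CPM against at most 52.8 and 7.27 CPM in CEN WT, while mcm3 was at 34.5 CPM against at least 47.9 CPM. Of 56 genes of gluconeogenesis and lipid metabolism 40 lay above 0, with a median of 0.37 (camera adjusted p 2.09e-06, adjusted p 0.452 with an estimated correlation), and with angptl4 and cpt1b of lowest p. Of these 6 passed adjusted over the list alone, 16 had an unadjusted p under 0.05, edgeR called 0 over all genes and DESeq2 4, and without CEN KO replicate 2 the median was 0.24. Mean log2 CPM of this list was 4.41, 4.84 and 4.71 in CEN KO against 4.17, 4.20 and 4.41 in CEN WT. Of 16 interrenal genes 15 lay above 0, median 0.53 (camera adjusted p 0.000475, adjusted p 0.736 with an estimated correlation), with the steroid synthesis gene cyp11a1 at 1.22 ± 0.46 (SE). Mean log2 CPM of the interrenal list was 3.63, 4.20 and 4.29 in CEN KO replicates 1, 2 and 3 against 3.66, 3.41 and 3.46 in CEN WT, so replicate 1 lay within the range of CEN WT, and that of the skeletal muscle list was 2.47, 3.45 and 5.23 against 3.14, 2.23 and 3.08. The C/EBP list, which includes cebpd itself at -1.94, had a median of -0.18 (camera adjusted p 0.00564, adjusted p 0.452 with an estimated correlation). Its median was -0.09 without CEN WT replicate 2 and -0.30 without CEN WT replicate 3 or CEN KO replicate 1. Adjusted over the list alone cebpd was the 1 member that passed. The others were ddit3 at -0.36 ± 0.16, cebpb at -0.36 ± 0.24, cebpz at -0.18 ± 0.15, cebpa at -0.03 ± 0.21, cebpg at -0.05 ± 0.10 and cebp1 at 0.14 ± 0.24 (SE).

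Transcripts of other tissues stood out in single CEN knockout libraries. Egg-coat transcripts of the gonad list were high in CEN KO replicate 1, with zp2.1 at 184 CPM and zp3b at 133 CPM, against 3.07 and 0.81 CPM in CEN KO replicate 2. Egg yolk protein transcripts, made in the liver of females, were high in CEN KO replicate 2, with vtg1 at 5340 CPM against 2.05 and 3.4 CPM in the other CEN KO libraries, although the labels describe male fish. Muscle transcripts were high in CEN KO replicate 3, with pvalb4 at 202 CPM against 7.77 and 26.7 CPM. The gonad list (median 4.79), the liver list (1.21, with apoa2 at 2.26 ± 0.56 and rbp4 at 0.98 ± 0.18, SE) and the skeletal muscle list (1.64, with acta1b at 1.64 ± 0.60, SE) passed camera with the preset correlation. Their adjusted p with an estimated correlation was 0.575, 0.788 and 0.788. Without CEN KO replicate 1 the gonad median was 0.90, without CEN KO replicate 2 it was 2.85 and the liver median -0.31, and without CEN KO replicate 3 the muscle median was 0.21. The liver median was 1.83, 1.91 and 2.06 without CEN WT replicates 1, 2 and 3 and 2.2 without CEN KO replicate 1.

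Of the other lists past camera, those of oxidative phosphorylation (median 0.15) and the proximal tubule (0.20) were higher, and erythroid genes (-0.27) and cytokines (-0.20) were lower. Their adjusted p with an estimated correlation was 0.944, 0.833, 0.944 and 0.788. Each lost its call when 1 library was left out. Medians were then 0.08 for oxidative phosphorylation without CEN KO replicate 3, 0.10, 0.08 and 0.17 for the proximal tubule without CEN WT replicate 1 and CEN KO replicates 2 and 3, and -0.24 and -0.10 for erythroid genes without CEN WT replicate 1 and CEN KO replicate 2. For cytokines they were -0.21, -0.11, -0.05, -0.19 and -0.14 without cebpd KO replicate 3, CEN WT replicates 1 and 2, and CEN KO replicates 1 and 3. Some medians grew where the call was kept. That of the proximal tubule was 0.35 without CEN WT replicate 3 and 0.31 without CEN KO replicate 1, and that of erythroid genes -0.48 without CEN KO replicate 1. The remaining 21 lists did not pass. Neutrophil genes had a median of -0.05 and heat shock genes one of -0.02, and the acute phase list had a median of 0.48 that was -0.28 without CEN KO replicate 2, and 0.91, 1.18 and 1.08 without CEN WT replicate 1 and CEN KO replicates 1 and 3, where it passed. Other lists that passed when 1 library was left out were the distal tubule (0.22, 0.21 and 0.28 without CEN WT replicates 2 and 3 and CEN KO replicate 1), endothelial cells (-0.11 without CEN WT replicate 3), and multiciliated cells and heart muscle (-0.09 and -0.78 without CEN KO replicate 3). Median and direction of the test differed in sign in 6 lists, none of them past the threshold.

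**Figure D4:**
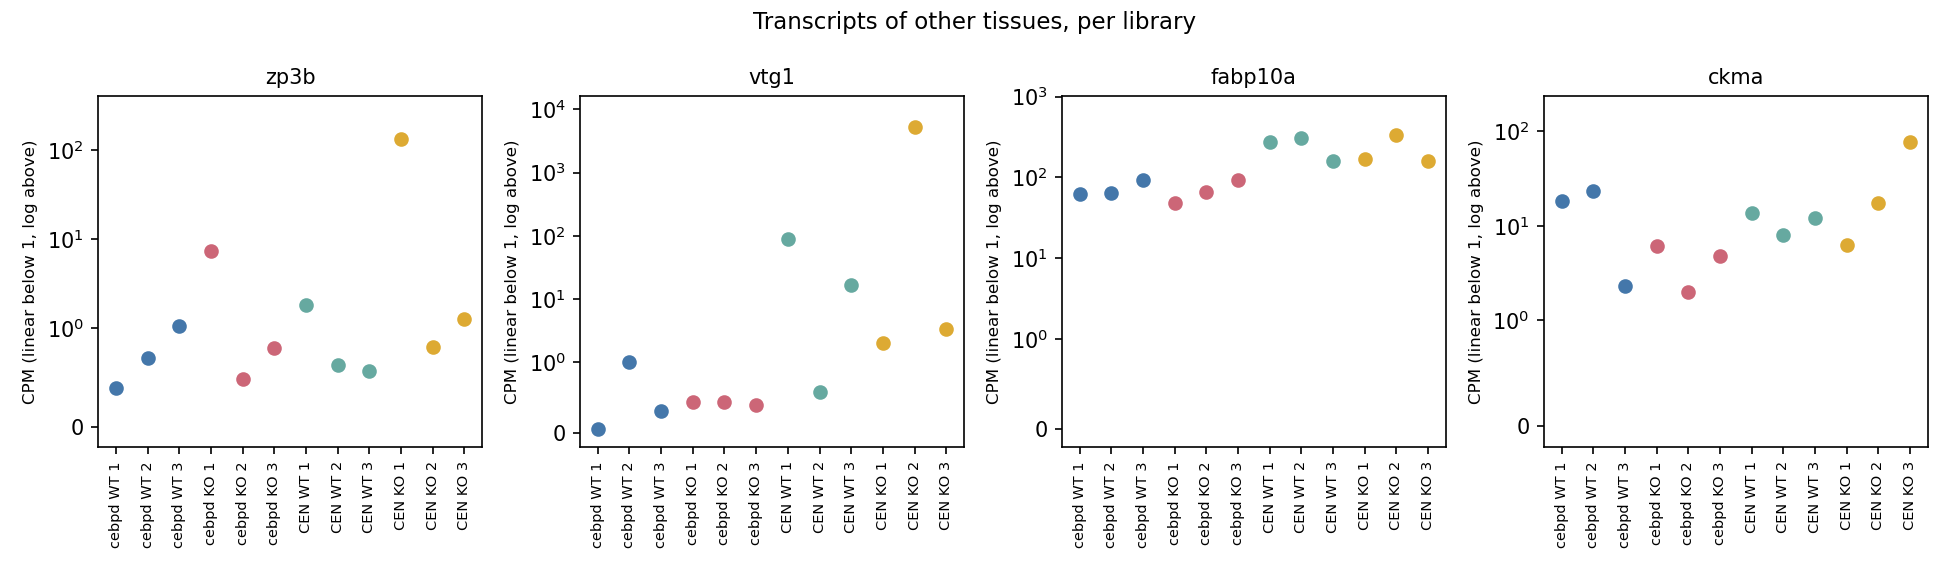
CPM (linear below 1, logarithmic above) of an egg-coat gene (zp3b), a yolk protein gene (vtg1), a liver fatty acid carrier gene (fabp10a) and a muscle creatine kinase gene (ckma) in each of the 12 libraries. zp3b peaked at 133 CPM in CEN KO replicate 1, vtg1 at 5340 CPM in CEN KO replicate 2 and ckma at 77.4 CPM in CEN KO replicate 3.

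Comparing the 2 knockouts, 5 genes differed in their effects by edgeR's test of the interaction and 0 genes were called in both in one direction. The 5 were akap2 (adjusted p 0.017), desi1a (0.0212), and cebpd, ggt1a and rbbp8 (0.0244 each). With the composition covariate 0 passed. With DESeq2 344 passed, with quality weights 487 and with the replicate block 129, the 5 among them each time. At an unadjusted p under 0.05, 54 genes were higher in both knockouts where independent lists give 46.6, and 43 were lower in both where they give 31.2. In opposite directions, 103 were lower in cebpd KO and higher in CEN KO where independent lists give 48.2, and 37 were higher in cebpd KO and lower in CEN KO where they give 30.2. With DESeq2 11 genes were called in both in one direction, with quality weights 10 and with the replicate block 5. With limma-voom, the composition covariate and the 6 libraries of each experiment 1 was, and without cebpd KO replicate 2 also 1. The log2 fold changes of the 11840 genes had a Pearson r of 0.428 across genes, which are not independent replicates, and a Spearman rho of -0.0776. Without CEN KO replicate 1, r was 0.0716, and without cebpd KO replicate 1 it was 0.162. Of genes with different effects there were 0 without cebpd WT replicate 2, cebpd KO replicate 1, CEN WT replicates 1 and 2 or CEN KO replicate 3, 2 without cebpd WT replicate 1 or cebpd KO replicate 2, 3 without cebpd WT replicate 3, 10 without CEN WT replicate 3, 12 without CEN KO replicate 2 and 48 without cebpd KO replicate 3.

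More genes differed between the 2 groups of wild types than between either knockout and its wild types. By edgeR's test 2961 of 11840 genes differed, 1287 higher and 1674 lower in CEN WT, and the number was 1630 without CEN WT replicate 1 and 1890 without cebpd WT replicate 3. The peptide transporter gene slc15a2 was at 144 CPM ± 16.2 in CEN WT and 16.7 CPM ± 0.79 in cebpd WT (SD, n = 3), with a log2 difference of 3.11 ± 0.21 (SE). fbxo25 (1.9 ± 0.14) and comtb (1.92 ± 0.15) were also higher in CEN WT (SE). unc119b (-3.34 ± 0.24), ggt1a (-3.35 ± 0.24), zgc:158445 (-6.69 ± 0.52), qars (-1.72 ± 0.13) and itgb1b.2 (-3.13 ± 0.24) were lower (SE). Of 47 heat shock genes 26 were lower in CEN WT and 1 higher, with a median of -0.71 (camera adjusted p 1.65e-12, adjusted p 0.0683 with an estimated correlation). Of 24 T and NK cell genes 10 were higher and 0 lower, median 0.81 (camera adjusted p 0.000219, adjusted p 0.654 with an estimated correlation). Of the 32 lists 9 passed camera with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.0683. cebpd itself differed by -0.42 ± 0.31 (SE) with an adjusted p of 0.354. The labels do not say whether fish line, day or batch differed between the experiments, so these cannot be told apart.

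Genes on the chromosome of cebpd were compared with all others, because a mutant allele is passed on together with its flanking haplotype, though the labels do not say where CEN lies. In the cebpd comparison 2 of 316 tested genes on it were called, cebpd and zgc:56530, and 8 of 11392 elsewhere (two-sided Fisher's exact test, p 0.0283), and with cebpd left out 1 of 315 (p 0.218). In the CEN comparison 1 of 316, rbbp8, was called on it and 0 of 11392 elsewhere (two-sided Fisher's exact test, p 0.027), and with cebpd left out 1 of 315 (p 0.0269). This p rests on 1 called gene and was 1 with the filter of 10 CPM, under which rbbp8 was not tested. With the replicate block the Fisher p of called genes on the chromosome in the CEN comparison was 0.26.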

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

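The tests on the chromosome share, on rbbp8, on the wild types and on the correlation were chosen after the results were seen, and the tests on gene order and on other splits before.

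The 2 knockouts differed in their effect on 5 genes by edgeR's test of the interaction (effect in cebpd KO minus effect in CEN KO). The log2 differences were -2.18 for akap2, -3.42 for cebpd, -1.79 for desi1a, -2.32 for ggt1a and 4.54 for rbbp8. Of 100 joint splits of the libraries within each experiment 3 gave as many genes, the real one included, so chance is excluded at that share for the count alone. The count holds cebpd, the mutated gene, and rbbp8, the 1 gene called in CEN KO. The share therefore does not speak for akap2, desi1a or ggt1a singly. Both akap2 and ggt1a already differed between the wild types, akap2 by -1.64 ± 0.18 (SE, CEN WT minus cebpd WT). For akap2 the cebpd wild types lay outside the range of all other libraries, so that group bears on its difference of effects. The count ran from 0 to 48 when 1 library was left out and was 0 with the composition covariate. The splits are ranked next. The highest split, with 7, kept the real groups and exchanged the wild-type and knockout labels of CEN, and the highest of the remaining 98 gave 5. By camera with the preset correlation 14 lists differed. The median differences were 0.65 for neutrophils, 0.42 for macrophages and monocytes, 0.33 for thrombocytes, 0.28 for blood stem and progenitor cells, 0.47 for the cell cycle and 0.25 for ribosomal proteins. They were -0.39 for the proximal tubule, -0.42 for the distal tubule, -0.25 for ion and water transport, -0.15 for glucocorticoid targets, -0.34 for heat shock, -0.45 for lipid metabolism, -1.03 for interrenal cells and -2.96 for skeletal muscle. None kept its call with an estimated correlation, where the lowest adjusted p was 0.436.

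Genes of low p gathered on the chromosome of cebpd in both comparisons, though the genes past the adjusted threshold in the cebpd comparison did not with cebpd left out (Fisher exact p 0.218). With cebpd left out, 30 of 315 tested genes on it (9.52%) had an unadjusted p under 0.01 in the cebpd comparison against 4.89% elsewhere, and 24 of 315 (7.62%) in the CEN comparison against 3.14% elsewhere. The larger Fisher exact p was 0.000877, with genes taken as independent, and the chromosome had the highest share of 25 in both. That lower cebpd transcript lowers rbbp8 is argued against, since rbbp8 was higher by 4.54 on the log2 scale in the effect of cebpd KO, which has less cebpd transcript, than in that of CEN KO. A candidate explanation is a flanking haplotype passed on with each mutant allele, though the labels do not say where CEN lies, nearness to cebpd in gene order stays open with one-sided permutation p of 0.0242 in the cebpd and 0.0893 in the CEN comparison, and an effect of the CEN lesion itself on rbbp8 was not tested.

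The cebpd wild types lay outside the range of the other 9 libraries in 8 of the 9 genes called in cebpd KO other than cebpd, all but hrasa, and these 8 differed between the wild types in the direction of the knockout. The 2 comparisons share the cebpd wild types, which are too few to halve, and part of the agreement may come from them. Independent lists give 1.21. In 20 simulations each experiment had its measured mean over wild types and knockouts together, so that the experiments differed and no knockout had an effect. Between the simulated wild types 2197 to 2332 genes passed, fewer than the 2961 measured. These simulations gave a mean of 4 and at most 7 of the 9 genes of lowest p (0 of 9 where no group differs, when almost no gene can pass). Across genes the fold changes had an r of 0.524, within the 0.461 to 0.533 of 20 simulations of unchanged groups, and a covariance of 0.271 against a simulated mean of 0.0695. Whether cebpd transcript level alone sets the 9 genes cannot be told from these values. The genes were picked by their gap to the same cebpd WT libraries, which can by itself move CEN WT towards cebpd KO. The pattern held for 8 of them, all but hrasa. In these CEN WT lay nearer to cebpd KO than to cebpd WT, with cebpd at 279 CPM in CEN WT and 9.1 CPM in cebpd KO. Yet cebpd differed between the wild types by only -0.42 ± 0.31 (SE, adjusted p 0.354 by edgeR's test). CEN WT minus cebpd WT was -4.39 ± 0.58 for rgs8 and -2.34 ± 0.32 for hsp90aa1.2 (SE). Between CEN WT and cebpd KO the 9 differed by -0.73 for hrasa to 0.31 for dnaja1. Of the 20 simulations in which the experiments differ 9 reached more than 4 of the 9 genes and 0 reached 8. An effect of cebpd beside other differences stays open, since the wild types of the experiments differ in 2961 genes. Handling or collection of the cebpd wild-type fish may account for their standing apart, and cannot be told apart from genotype, since the labels give no batch or day. The lowest cebpd WT library lay above the highest of the other 9 by 0.336 in mean log2 CPM of the heat shock list. That list holds hsp90aa1.2 and dnaja1, which are among the 9 genes, so the gap is not separate support.

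The Pearson r of 0.428 between the 2 sets of fold changes may rest on egg-cell transcripts in 1 knockout library of each experiment. zp2.1 was at 184 CPM in CEN KO replicate 1 and 7.73 CPM in cebpd KO replicate 1, and at 4.12 CPM or less in the other 10 libraries, with zp3b, zar1 and buc at 133, 135 and 115 CPM in the first and 7.29, 5.01 and 8.34 CPM in the other, and 13 of the 20 gonad genes reach 1 CPM in wild types. Without these 2 libraries r was -0.047. Relabelled libraries gave an r of at least this size in 49 of 100 joint splits, the real one and that with the CEN labels exchanged included, with 0.595 the highest of the others, so chance is not excluded. The Spearman rho of -0.0776 does not speak for a shared response to lower cebpd, since only 33 of the other splits gave a lower one. Such a response stays open, as the splits ran from -0.306 to 0.306. At an unadjusted p under 0.05, 103 genes were lower in cebpd KO and higher in CEN KO (independent lists 48.2), and 37 the reverse (30.2). In one direction, 43 were lower in both (31.2) and 54 higher (46.6).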

How the results depend on the processing

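The log2 fold change of cebpd in cebpd KO kept its call in all 25 alternatives (-5.70 to -5.01), with -5.68 and -5.01 the extremes when leaving out 1 library, while that in CEN KO stayed between -2.11 and -1.79, also the extremes without 1 library, and its side of the threshold differed in 6 of 25. Robust edgeR, quality weights, joint removals of libraries and the chromosome test at an unadjusted p were chosen after seeing the data. With DESeq2, which made more false calls on simulated data, 410, 137 and 344 genes passed in cebpd KO, CEN KO and their difference and 11 in both in one direction, and cebpd in CEN KO passed at -1.94. With limma-voom the CEN and difference counts were 5 and 8, both in one direction 1, r 0.224 and cebpd in CEN KO -1.92. With quality weights, which gave cebpd KO replicate 3 a weight of 0.176, they were 351, 193, 487 and 10, r 0.17 and cebpd in CEN KO -1.98. With the filter of 10 CPM the cebpd and CEN counts were 63 and 2, r -0.123, and the Fisher p of called genes on the chromosome in CEN KO 1, since rbbp8 was not tested. With the composition covariate they were 2, 66 and 0, both 1, r 0.23 and cebpd in CEN KO -2.05, and list medians changed to 0.16 (lipid metabolism, cebpd KO), 0.17 (muscle, cebpd KO), -0.0322 (proximal tubule, CEN KO) and 0.14 (erythroid, CEN KO). The proximal tubule and erythroid lists are part of that covariate, so a change of their medians is partly built into the fit. With only the 6 libraries of an experiment the cebpd and CEN counts were 1 and 2, both 1, r -0.0198 and cebpd in CEN KO -1.94. With the replicate block counts were 197, 11, 129, 1544 between wild types and 5 in both, and the chromosome p in CEN KO 0.26. Same-numbered deviations correlated at 0.3, -0.01 and 0.37 in the cebpd and 0.2, -0.02 and 0.16 in the CEN experiment. Replicates 1 and 3 of both knockouts correlated best with their own number and replicate 2 did not. Whether the numbers pair the libraries thus stays open. Without cebpd KO replicate 3 and CEN KO replicate 1 counts were 241, 9 and 126, r 0.0509, and medians in cebpd KO -0.17 (oxidative phosphorylation) and -0.0317 (ribosomal). Without cebpd KO replicate 3 and CEN KO replicate 2 they were 126, 2 and 79, with -0.149 and -0.007, and -0.296 for acute phase in CEN KO. Without replicate 1 of both knockouts r was -0.047, and Spearman's rho was -0.0776. At an adjusted p under 0.1 counts were 134, 4 and 8, and with a log2 change of at least 1 the wild types gave 1145. Lists past the threshold were 1 and 0 with an estimated correlation and 3 and 0 with fry. The 3 were the heat shock, neutrophil and C/EBP lists in cebpd KO. Leaving out 1 library gave 1 to 233 (cebpd KO), 1 to 7 (CEN KO), 0 to 48 (difference), 1630 to 4013 (wild types), 0 to 1 (both), r 0.0716 to 0.548, and 11 to 16 and 9 to 13 lists. Medians of lists that turned ran over -0.48 to 0.27 (erythroid), -0.23 to 0.25 (cell cycle), -0.15 to 0.18 (oxidative phosphorylation) and -0.00771 to 0.404 (ribosomal) in cebpd KO, and -0.28 to 1.18 (acute phase) in CEN KO. Except for the filter the cause was not tested. List tests were not run for DESeq2, limma-voom or robust edgeR. Genes changed 1.5-fold were rarely recovered on simulated data at this depth and number of libraries.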

Other observations

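The test of read shares below was chosen after the values were seen, and the counts of other splits were planned.

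The yolk protein transcript vtg1 was also seen in 2 CEN wild types, at 88.1 CPM in replicate 1 and 16.8 CPM in replicate 3 against 0.575 CPM in replicate 2, while the 6 libraries of the cebpd experiment had at most 1.01 CPM of it. Other yolk protein genes differed from this, with vtg5 at 23 to 79.4 CPM and vtg6 at 9.75 CPM or more in the cebpd experiment, and vtg5 at 32.6, 7.27 and 34.9 CPM in the CEN wild types. Of the gonad list 13 of 20 tested genes reached 1 CPM in wild types.

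Across the 12 libraries the share of reads in more than 1 gene rose with the mean log2 CPM of the erythroid list, with a Pearson r of 0.866 (permutation p 0.00029, adjusted 0.00058) and a Spearman rho of 0.804 (permutation p 0.00239, adjusted 0.00478). Without cebpd WT replicate 2 and CEN KO replicate 2, the libraries farthest from the median, r was 0.633, and within the cebpd and CEN experiments it was 0.906 and 0.958. The share of reads in no gene had an r of -0.572 (permutation p 0.051, adjusted 0.051) and a rho of -0.42 (permutation p 0.177, adjusted 0.177), and an r of -0.0998 without those libraries. These were the 2 relations computed. The globin gene hbaa1 ranged from 6230 CPM in CEN KO replicate 2 to 26100 CPM in cebpd WT replicate 3.

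Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 10 genes in the cebpd comparison and the highest other split 0, with 1 split as large. In the CEN comparison the real split gave 1 gene and the highest other 1, with 2 splits as large. Between wild types the real split gave 2961 genes and the highest other 0, with 1 split as large. For lists past camera the real split gave 15 in the cebpd comparison and the highest other 15, with 3 splits as large, and 11 in the CEN comparison and the highest other 20, with 9 splits as large. For genes called in both in one direction the real count was 0, which all 100 joint splits reach by definition, with 0 the highest of the others, so the splits say nothing about it.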
